A study of Mus musculus with 18 samples.

How the data were processed

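The series holds 18 ATAC-seq libraries of mouse embryonic stem cells, 3 at each of 0, 3, 6, 12, 24 and 48 h after auxin and dTAG13, grouped by the time stated in the labels. Per the labels' protocols, nuclei of 100000 cells were isolated by lysis for 3 min and exposed to 120 nM transposase for 30 min at 37 °C, and libraries were made with 5 cycles of preamplification and 5 further cycles. The series describes the repeats as biological. The submitters' processing notes name Trimmomatic 0.36, Bowtie2 2.4.2 and MACS2 2.2.7.1 and the mouse builds mm10 and GRCm38, with no role or order. How the peaks of the libraries were merged, the peak threshold, and whether duplicates, blacklisted regions and the offset of transposase insertions were treated is not given in the sources used here. An offset of insertions would move peak edges by a few bases, whereas a threshold or duplicate filter could change which peaks exist.

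The deposited values are positions of 166066 merged peaks, with a chromosome, start, end and a name that repeats the position in all 166066 cases. No 2 peaks overlap, the smallest gap on assembled chromosomes is 1 bp, and widths run from 198 to 10001 bp. The file holds no count, height, score or library, so depth and precision per library are unknown. The tests planned on libraries or values per peak, including each later time against 0 h, were therefore not run, and 0 columns of values per sample were left unused. Of the peaks, 165744 lay on assembled chromosomes and entered the analysis, 322 lay on 41 unplaced or unlocalised contigs, and 0 lay on the mitochondrial genome.

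Gene positions came from a RefSeq gene table of GRCm38.p6, the same build as mm10, which holds 49997 genes, gives no strand and was used without genome sequence. From the rows under chromosome names, 348 genes, 113 of them protein-coding, were left out because their coordinates are those of scaffolds or patches. Genes not listed under an autosome, X or Y were left out as well, which left 49595 genes and 21774 protein-coding genes. The plan called for the 5′ end of each gene. Without strand, a gene end was instead defined as a window of 500 bp either side of the annotated start or end, and a gene counted as having a peak where any peak overlapped either window by at least 1 bp. Exons and introns were not told apart, shuffled positions did not avoid unsequenced bases, and repeat content and promoter CpG content were not analysed here.

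The share of protein-coding genes with a peak was compared with 100 seeded shuffles that moved each gene's pair of windows at random within the span of peaks on its chromosome. For 23 gene lists fixed before the data were examined, genes with a peak at an end were compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. List genes were matched by symbol or, for 3, by synonym, and 10 list genes were not tested because they are not protein-coding or lie on a scaffold. Gene-body density was the number of peak midpoints per 100 kb of gene, and each list's median was placed among 10000 random lists of the same size matched on decile of gene length, with a two-sided p and the same adjustment. Peaks were assigned by midpoint to gene end, gene body or intergenic DNA, in that order. Shares carry 95% Wilson intervals. Genes are not independent replicates, and neighbours can share a peak, so p-values describe this peak set and not differences between cultures. Named genes follow a rule fixed in advance: the 3 methyltransferase genes, up to 4 members of each other list with a peak and up to 4 without in list or alphabetical order, the genes nearest the 10 widest peaks, and the 10 genes of at least 10 kb with the most peaks per 100 kb.

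Alternatives set in advance were windows of 250 and 2000 bp, an overlap of at least 200 bp, and only peaks wider than the median of 578 bp. Chosen after seeing the data were a background without olfactory and vomeronasal receptors, 10000 random lists matched on gene length, 9999 rotations of each list along the gene order, gene bodies without 2 kb at both ends, peaks more than 2000 bp from any gene end for chromosome densities, and windows of 2000 bp for peak widths. The list test was tested on simulated peaks over the 21774 genes. It called a list of 50 genes set to 5% (adjusted exact p = 3.46e-16) and 1 set to 90% (adjusted p = 0.00678) against others at 63.5% and 63.3%, did not call a list set to 30% (adjusted p = 0.0571), and called 0 of 20 unchanged lists. All 13089 placed gene ends were found, which was certain because each simulated peak was centred on its gene end. The 20 unchanged lists held genes drawn at random, so they do not test lists of neighbouring genes. In the simulation windows also caught peaks of neighbouring genes, so 22 of 50 genes of the 30% list had a peak where 17 had been drawn. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.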

Results

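Accessible chromatin was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in mouse embryonic stem cells built to study the loss of 3 histone H3 lysine 9 methyltransferases. The labels give the genotype as floxed Suv39h1, deleted Suv39h2 and floxed Setdb1, and state that auxin at 100 µg/ml and dTAG13 at 0.5 µM, both of which trigger degradation of suitably tagged proteins, were added to the medium. The labels do not say which protein carries a tag, so removal of Suv39h1 and Setdb1 is taken from the stated purpose and was not checked. Cells were collected at 0, 3, 6, 12, 24 and 48 h, with 3 biological repeats per time and 18 libraries in all, and 0 h is the stated baseline for asking where chromatin opens after ablation of the enzymes. The values analysed here are 1 list of 166066 merged peaks over all libraries, which together cover 117 Mb. The list gives positions only, with no library, read count, height or score, so gains and losses after 0 h were not analysed here, sequencing depth is unknown, and no value below has an error between replicates. Every result therefore describes where chromatin was called open over the pooled libraries, and the 95% intervals of shares are Wilson intervals over genes or peaks that cover counting error only.

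The genes of the 3 enzymes each had a peak over an annotated end. Suv39h1 (chromosome X, 8061171 to 8074760, GRCm38) had a peak of 1409 bp at 8073854 to 8075262, Suv39h2 (chromosome 2, 3455815 to 3474986) 1 of 1682 bp at 3474085 to 3475766, and Setdb1 (chromosome 3, 95323525 to 95357202) 1 of 1205 bp at 95356204 to 95357408. In each of them the peak lay across the higher-coordinate end of the gene. A peak at the gene does not measure the enzyme, so these values do not check the labels.

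Across the genome, 15550 of 21774 protein-coding genes (71.4%, 95% interval 70.8 to 72.0) had a peak within 500 bp of either annotated end. The same pairs of windows moved at random along their chromosomes had a peak in 19.7% ± 0.247 of cases (SD over 100 shuffles), a 3.63-fold difference, and 0 of the 100 shuffles reached the observed share (permutation p = 0.0099, one-sided, the smallest that 100 shuffles can give). With windows of 2000 bp the shares were 79.7% and 40.4%, a smaller ratio. Both ends had a peak in 3957 genes (18.2%). From the gene end outwards, coverage by peaks was highest at the end itself, where 63.6% of genes had a peak over it. It was 20.4% at 1 kb and 14.7% at 5 kb outside, and positions inside genes were not scanned. The gene table carries no strand, so the promoter end could not be told from the other end and a peak of a neighbouring gene can count. It gives a single start and end per gene, so a peak at a promoter inside the gene, away from both ends, is not counted.

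Of 23 gene lists fixed in advance, 8 had peaks at gene ends more often than other protein-coding genes, 6 less often, and 9 did not pass the test (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over the 23 lists). All 25 pluripotency genes had such a peak (adjusted exact p = 0.00107), among them Pou5f1, Nanog and Sox2, core transcription factors of the pluripotent state, and Klf2, a factor of naive cells. The peak at Pou5f1 (chromosome 17, 35506032 to 35510777) was 2567 bp wide and that at Sox2 (chromosome 3, 34649995 to 34652461) 2470 bp. All 20 housekeeping genes, including Actb, Gapdh, Tbp and Hprt, also had one (adjusted exact p = 0.00409). Ribosomal protein genes had a peak in 77 of 80 cases (96.3%, 89.5 to 98.7, adjusted exact p = 5.16e-08), with Rpl17, Rpl32l and Rps27l as the exceptions.

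Genes that are typically silent outside the germ line also had open ends in the pooled set. Germline and meiotic genes had a peak in 32 of 35 cases (91.4%, 77.6 to 97.0) against 71.4% of other genes (odds ratio 4.28, adjusted exact p = 0.0135). They included Dazl, an RNA-binding regulator of germ cells (chromosome 17, 50279393 to 50293620), Ddx4, the Vasa helicase, Mael, a factor of the piRNA pathway, and Sycp1 of the synaptonemal complex, whose peaks were 1226, 908, 955 and 1290 bp wide. Taf9b, Tdrd9 and Piwil2 had none within 500 bp, and their nearest peaks lay 0.745, 1.47 and 0.791 kb from an end. The call was lost against random lists matched on gene length (adjusted permutation p = 0.102) and against a background without receptor genes (adjusted exact p = 0.0677).

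Zinc finger genes of the Zfp series, many of which encode C2H2 proteins that recruit H3K9 methylation, had a peak at an end in 339 of 367 cases (92.4%, 89.2 to 94.7, odds ratio 4.93, adjusted exact p = 1.19e-22). Zfp1, Zfp101, Zfp105 and Zfp106 were covered by peaks of 1036 to 1329 bp, whereas the nearest peaks to Zfp352, Zfp217, Zfp235 and Zfp366 lay 0.693 to 1.74 kb from an end. Genes of the H3K9 methylation and HP1 machinery had a peak in 27 of 30 cases (90%, 74.4 to 96.5, odds ratio 3.61, adjusted exact p = 0.0406), among them the HP1 genes Cbx1, Cbx3 and Cbx5 and the corepressor gene Trim28. The exceptions were Dnmt1, the maintenance DNA methyltransferase, Dnmt3l, a cofactor of the de novo enzymes, and the demethylase Kdm4c, with nearest peaks at 0.921, 0.573 and 1.01 kb. The bodies of Dnmt1, Dnmt3l and Kdm4c held 10, 5 and 11 peaks, and the nearest peaks of Dnmt1 and Dnmt3l lay inside the gene. A promoter inside the annotated gene could thus be open in them. The call for the machinery list did not hold with the list rotated along the gene order (adjusted permutation p = 0.0527), matched on gene length (0.313 by permutation) or without receptor genes in the background (exact p = 0.124, adjusted), nor with windows of 250 bp (0.0708), an overlap of 200 bp (0.0756) or wide peaks alone (0.0778).

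Clustered gene families differed in how firmly their shares stood. Histone genes, the linker histone genes H1f0, H1f1, H1f10 and H1f2 among them, had a peak in 65 of 67 cases (97.0%, 89.8 to 99.2, odds ratio 13.1, adjusted exact p = 2.47e-07), with H1f6 and H1f7 as the exceptions. Clustered protocadherins, cell adhesion molecules of neurons, had one in 50 of 57 cases (87.7%, 76.8 to 93.9, odds ratio 2.86, adjusted exact p = 0.00946). Rotating each list along the gene order, which keeps neighbours together, gave adjusted permutation p = 0.133 for the histones and 0.416 for the protocadherins. The protocadherin call was also lost with matching on gene length (adjusted permutation p = 0.102), without receptor genes (exact, 0.0677) and with wide peaks alone (exact, 0.0760).

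**Figure D1:**
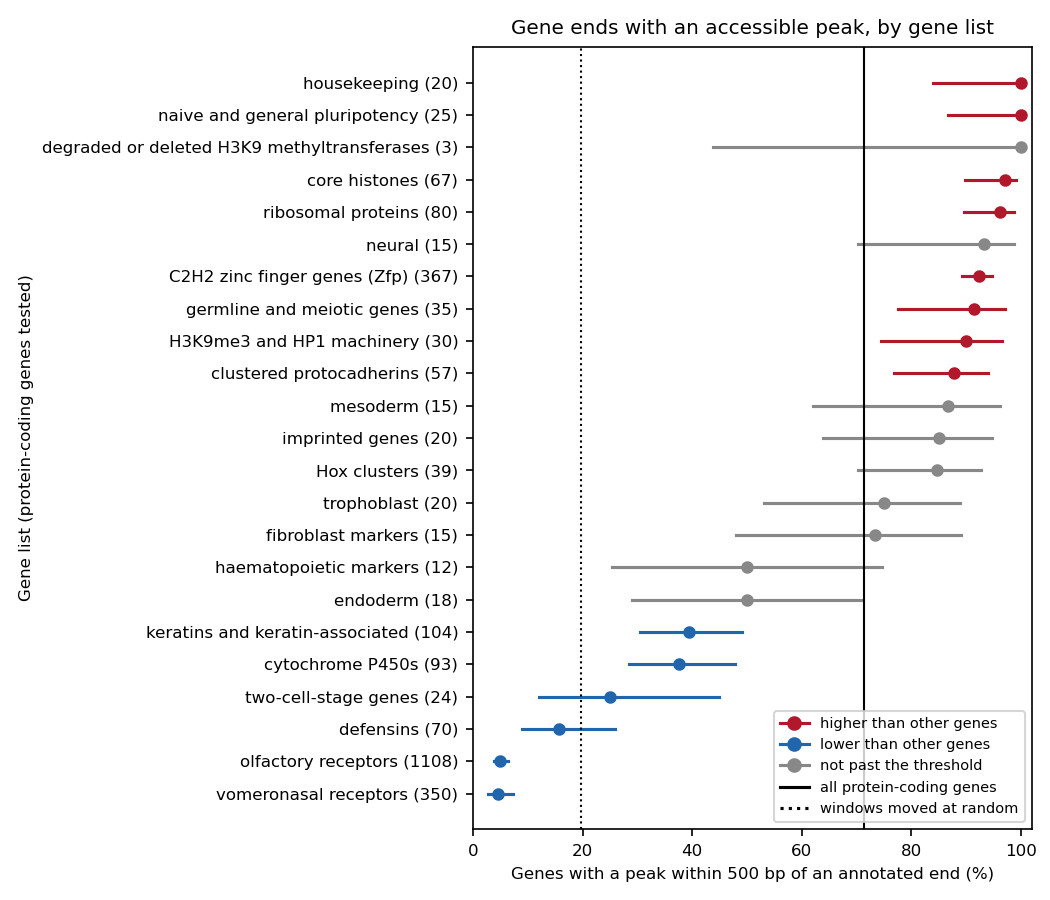
The share of genes with a peak within 500 bp of an annotated end (x axis, %) is plotted for the 23 fixed lists (y axis, number of protein-coding genes tested in parentheses), with points coloured by the Fisher's exact test and bars giving 95% Wilson intervals, and the solid and dotted lines mark 71.4% for all protein-coding genes and 19.7% for windows moved at random. Housekeeping and pluripotency genes sit at 100%, and olfactory and vomeronasal receptors at 4.96% and 4.57%.

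Chemosensory receptor genes had the lowest shares of the 23 lists. Olfactory receptors had a peak at an end in 55 of 1108 cases (4.96%, 3.83 to 6.41) against 75% of other genes (odds ratio 0.0174), and vomeronasal receptors, which detect pheromones, in 16 of 350 cases (4.57%, 2.83 to 7.30, odds ratio 0.0182, adjusted exact p = 3.80e-159). The p of the olfactory list was too small for the software to represent. Both shares lay below the 19.7% of windows moved at random, but those pairs were spaced as in all protein-coding genes. Receptor genes are short, with medians of 951 bp (olfactory) and 960 bp (vomeronasal), so their windows span less DNA. Random lists matched on gene length had 39.9% and 46.1%, and both calls held against them (adjusted permutation p = 0.000657 for each). Olfr1000 (chromosome 2, 85607964 to 85608908) had its nearest peak 46.3 kb away, Olfr1002 47.3 kb, Olfr1006 16.9 kb and Olfr10 8.29 kb away, whereas Olfr1, Olfr113, Olfr1166 and Olfr1342 had a peak within 0.265 kb of an end. A region of 250 kb on chromosome 2 with 8 olfactory receptor genes held 2 peaks, and 1 of the same length around Nanog held 57. Both regions were picked by hand and neither stands for a typical stretch, as the autosomal median was 65.9 peaks per Mb.

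Genes of the 2-cell stage, a set that includes the totipotency-associated Zscan4 family, had a peak at an end in 6 of 24 cases (25.0%, 12.0 to 44.9, odds ratio 0.133, adjusted exact p = 8.33e-06). Duxf3, which encodes the DUX activator of that stage, had a peak of 2201 bp over its end (chromosome 10, 58229505 to 58233089), and Sp110, Arg2 and Pramel11 also had one. Zscan4b, Zscan4c, Zscan4d and Zscan4f had none, with nearest peaks 3.14 to 7.65 kb away. Much of this list lies in multi-copy families whose reads cannot always be placed, so these absences are uncertain, as are peaks at members of such families.

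Several families of differentiated tissues also had few open ends. Defensins, antimicrobial peptides of epithelia, had a peak in 11 of 70 cases (15.7%, 9.01 to 26.0, adjusted exact p = 2.28e-21), cytochrome P450 genes in 35 of 93 (37.6%, 28.5 to 47.8, adjusted exact p = 6.00e-11), and keratin genes in 41 of 104 (39.4%, 30.6 to 49.0, adjusted exact p = 6.66e-11). Among members without one, the nearest peak lay 0.875 kb from Defa17 and 5.62 to 6.80 kb from Defa2, Defa20 and Defa21. It lay 1.68 to 4.91 kb from Cyp17a1, Cyp19a1, Cyp11b2 and Cyp11b1, genes of steroid synthesis, and 0.717 to 1.85 kb from Krt17, Krt2 and Krt15 but 16.2 kb from Krt13. Cyp11a1, Cyp20a1, Krt10 and Krt14 had a peak at an end. Fisher's test treats neighbours as independent. Rotating each list along the gene order, which keeps neighbours together, gave weaker calls for defensins, P450 genes and keratins (adjusted permutation p = 0.0151, 0.00138 and 0.0393). Against random lists of matched gene length the keratin call was lost (46.1% in those lists, adjusted permutation p = 0.193).

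Lineage markers that did not pass the test spanned a wide range. Neural genes, including Pax6, Sox1, Nes and Olig1, had a peak at an end in 14 of 15 cases (adjusted exact p = 0.112), with Gfap as the exception. Mesoderm genes had one in 13 of 15 (adjusted exact p = 0.297), with Myf5 and Meox1 lacking it, imprinted genes in 17 of 20 (adjusted exact p = 0.268), with Igf2, Snrpn and Impact lacking it, and Hox genes in 33 of 39 (adjusted exact p = 0.109). Trophoblast genes had one in 15 of 20 (adjusted exact p = 0.847), among them Cdx2, Eomes and Elf5, while the nearest peaks lay 1.78 and 2.67 kb from Esx1 and Psg17 and 33.4 and 16.0 kb from the prolactin family members Prl3d1 and Prl2c2. Endoderm genes had one in 9 of 18 (adjusted exact p = 0.0978), and that list passed as lower with matching on gene length (adjusted permutation p = 0.0477) and without receptor genes (exact, 0.0412). With windows of 2000 bp its direction turned, to 83.3% against 79.7% of other genes (adjusted exact p = 1.00). The trophoblast share turned lower with wide peaks alone (55.0% against 66.7%) and without receptor genes (75% against 76.2%), and passed in neither. Markers of other cells that the culture could hold also lay among these lists. Fibroblast genes had a peak in 11 of 15 cases (adjusted exact p = 1.00), with nearest peaks 1.95 to 5.72 kb from Col6a1, Lum, Col3a1 and Postn, and haematopoietic genes in 6 of 12 (adjusted exact p = 0.146), with nearest peaks 0.887 to 4.35 kb from Cd8a, Ptprc and Hbb-bs. The fibroblast share, 73.3% against 71.4% of other genes, turned lower in 5 of the 7 alternatives and passed in none. Rotation, 1 of the 7, cannot turn a share. The haematopoietic list passed as lower with windows of 250 bp (adjusted exact p = 0.0201) and with wide peaks alone (0.0467). The Hox and imprinted lists passed as higher with windows of 2000 bp (adjusted exact p = 0.000437 and 0.0311). The 3 methyltransferase genes are too few to pass (adjusted exact p = 0.616), and genes of a list are not independent replicates.

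**Figure D2:**
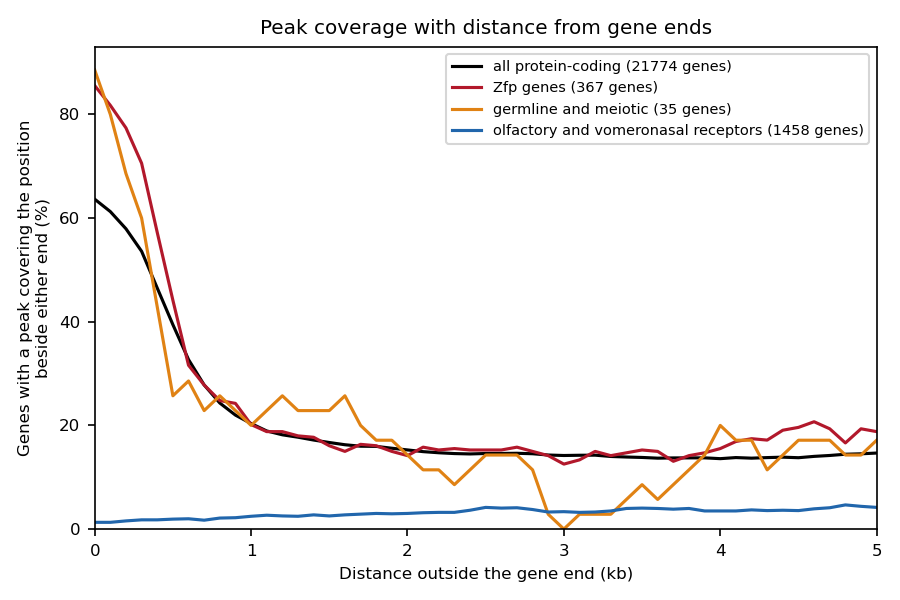
The share of genes with a peak covering the position at a given distance outside either gene end (y axis, %) is plotted against that distance (x axis, kb) for all protein-coding genes, Zfp genes, germline and meiotic genes, and both receptor families together. At the end itself the shares were 63.6%, 85.6%, 88.6% and 1.30%, and at 5 kb 14.7%, 18.8%, 17.1% and 4.18%.

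**Figure D3:**
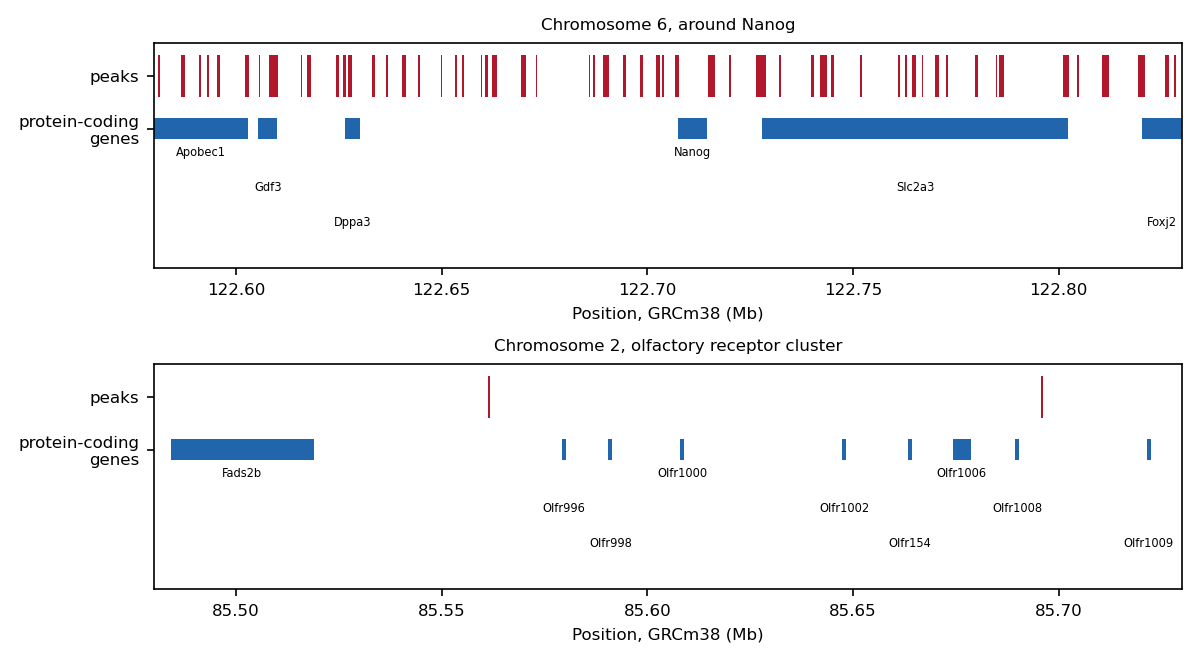
Merged peaks (red) and protein-coding genes (blue) are drawn to scale by GRCm38 position (x axis, Mb) in 2 regions of 250 kb picked by hand. The region around Nanog on chromosome 6 holds 57 peaks, and the olfactory receptor cluster on chromosome 2 holds 2.

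Within gene bodies, Hox, pluripotency and clustered protocadherin genes carried denser peaks than other genes of their length. Hox genes had a median of 33.9 peaks per 100 kb of gene body against 14.1 in random lists matched on gene length, pluripotency genes 25.2 against 11.1, and clustered protocadherins 25.1 against 6.78 (adjusted permutation p = 0.00153, 0.00230 and 0.00153, two-sided, from 10000 random lists). The random lists draw scattered genes, whereas Hox and protocadherin genes lie in clusters, so their p-values may be too small. Rotation along the gene order was not run for gene bodies. At gene ends it moved the adjusted p of protocadherins from 0.00946 (exact) to 0.416 (permutation). Cytochrome P450 genes had fewer, 4.63 against 11.9 (adjusted permutation p = 0.00153). The H3K9 methylation and HP1 machinery had 14.5 against 9.89 (adjusted permutation p = 0.0497), a call lost when only peaks wider than the median were counted (adjusted permutation p = 0.438). Zfp genes had 12.7 against 11.7 (adjusted permutation p = 0.206) and germline genes 8.11 against 9.54 (adjusted permutation p = 0.691). Counting only peaks wider than the median, Zfp genes passed as higher (8.10 against 6.64, adjusted permutation p = 0.00230), as did imprinted (12.9 against 4.61, 0.00644), mesoderm (25.1 against 2.36, 0.0169) and neural genes (24.8 against 4.67, 0.0345). None of those 4 lists passed with 2 kb removed at both ends, where Zfp genes had 7.80 against 8.53 (adjusted permutation p = 0.440). The other 3 stood at 11.7 against 8.13 in 13 imprinted, 17.0 against 6.67 in 6 mesoderm and 17.1 against 4.93 in 7 neural genes, which are fewer genes than over whole bodies (adjusted permutation p = 0.398, 0.152 and 0.182). With 2 kb removed at both ends, a setting chosen after seeing the data, 32 germline genes had 3.84 against 8.33 (adjusted permutation p = 0.0146, lower), 16 trophoblast genes 17.5 against 3.64 (0.0146, higher) and 131 vomeronasal receptor genes 0 against 8.69 (0.00153, lower). With wide peaks alone, the germline and trophoblast lists did not pass, at 5.14 against 4.99 and 11.1 against 6.87 (adjusted permutation p = 1.00 and 0.317). Over whole bodies the test says nothing of receptor, histone, defensin and keratin genes, whose medians were 0 in the lists and in the random lists alike, and the alpha protocadherin genes share 1 annotated end, so their bodies overlap.

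Among genes of 10 kb or more, those with the most peaks per 100 kb were Irx4 (49.8, 5 peaks), a homeobox gene, Zscan10 (49.0, 5 peaks), a zinc finger gene of stem cells, Cbx6 (47.9, 5 peaks), which encodes a Polycomb protein, and Six3 (47.7, 6 peaks), a homeobox gene of the forebrain and eye. Caly, Plaur, Gpat2, Slc9a3r2, Dpf1 and Fkbp3 followed with 43.5 to 47.3. The median over all protein-coding genes was 9.54, and 76.2% of genes held at least 1 peak midpoint.

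Peaks were concentrated at gene ends and thinner between genes. By midpoint, 11.5% of the 165744 peaks on assembled chromosomes (11.3 to 11.7) lay within 500 bp of an annotated end of a gene of any kind, against 3.46% ± 0.0432 for positions moved at random (SD over 100 shuffles), a 3.32-fold difference. The difference was 1.97-fold with windows of 2000 bp and 5.13-fold for peaks wider than the median. Gene bodies held 49.7% (49.4 to 49.9) against 46.9% ± 0.118, and intergenic DNA held 38.8% (38.6 to 39.1) against 49.7% ± 0.120. The small excess in gene bodies did not hold in the alternatives. Their share was 42.3% against 42.1% with windows of 2000 bp and 46.6% against 46.9% for peaks wider than the median, both within the range of the shuffles. None of the 100 shuffles reached the observed share of gene-end peaks, with a highest value of 3.55%.

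Gene-end peaks were wider than the others. Their median width was 1050 bp (quartiles 625 and 1413) against 549 bp in gene bodies and 542 bp in intergenic DNA, and 77.3% of them (76.7 to 77.9) exceeded the overall median of 578 bp. The share of peaks near a protein-coding end was 2.82% for peaks of up to 500 bp, 30.9% at 1 to 2 kb and 57.0% (49.3 to 64.3) at 3 to 4 kb. Of the 26 peaks over 4 kb on assembled chromosomes, 4 (15.4%, 6.15 to 33.5) lay near one. The widest peak of the set, 10001 bp on chromosome 3 at 6297553 to 6307553, lay 308 kb from its nearest protein-coding gene, 1700008P02Rik. Others among the 10 widest lay within Klhdc4 (5724 bp) and Sik3 (5646 bp), 201 kb from Lama2 (7059 bp) and 152 kb from Nup35 (5415 bp), and 3 lay 13.8 to 54.3 kb from Gm21119 on chromosome 8. Merging over 18 libraries can widen peaks, so these widths are those of the merged intervals.

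Chromosome X had a lower peak density than any autosome. It had 31.9 peaks per Mb between its first and last peak, 0.484 times the autosomal median of 65.9, and the 19 autosomes ranged from 53.0 on chromosome 3 to 107 on chromosome 11. Away from gene ends, by more than 2000 bp, X had 24.7 peaks per Mb against 40.5 to 77.3 on the autosomes. Chromosome Y had 290 peaks, or 3.20 per Mb. X held 3.23% of peaks on assembled chromosomes (3.15 to 3.32). No test was made, since each chromosome gives 1 value, and these densities are per Mb of reference sequence that includes unsequenced gaps.

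**Figure D4:**
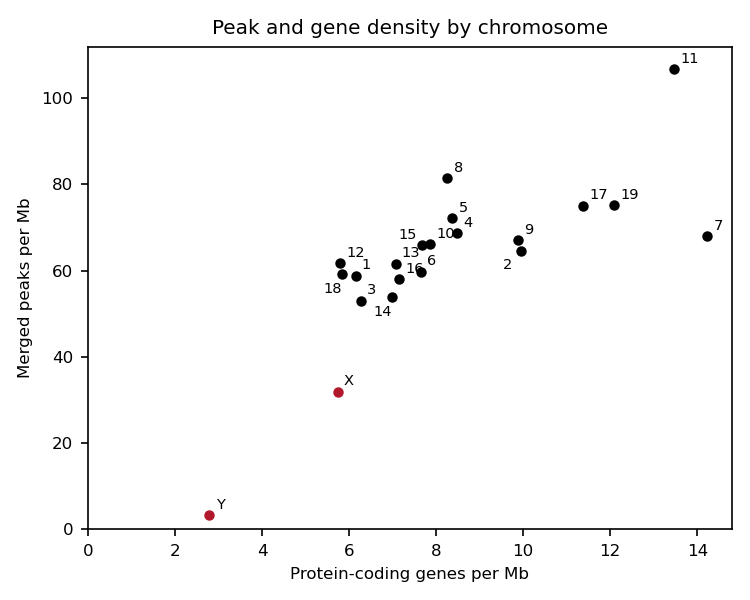
Merged peaks per Mb (y axis) are plotted against protein-coding genes per Mb (x axis) for each chromosome, with the sex chromosomes in red. X, at 31.9 peaks per Mb, and Y, at 3.20, lie below the 19 autosomes, which range from 53.0 to 107.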

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

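No group could be examined for outlying libraries or for differences between times, as the merged list names no library. The 1 result singled out concerns sequence outside the main analysis: 322 peaks lay on 41 unplaced or unlocalised contigs, where no gene list was tested. A single unplaced contig held 35 of them, with a median width of 1057 bp and a widest peak of 9188 bp, against an overall median of 578 bp on assembled chromosomes. The 0 h libraries cannot be told apart in the list, so these peaks have no control to be set against.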

How the results depend on the processing

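The excess of peaks at protein-coding gene ends kept its direction and passed under all 4 alternatives set in advance (66.7% with wide peaks alone to 79.7% with windows of 2000 bp), and the number of lists called, 14, became 11 to 16 over the 7 alternatives, of which the background without receptors, length matching and rotation were chosen after seeing the data. No list that had passed changed direction, whereas the endoderm, trophoblast and fibroblast lists, which had not passed, did under 1, 2 and 5 of the 7. Rotation leaves the compared shares as they were, so no direction could change under it. The number of lists called in gene bodies was 5 and became 8 with wide peaks alone and 8 without 2 kb at both ends, the latter testing fewer genes; the cause was not tested. With windows of 2000 bp, the share of gene-end peaks wider than the median moved from 77.3% to 65.7%, a class that then takes in more flanking peaks, and the X share of peaks moved from 3.23% to 3.33% for peaks over 2000 bp from gene ends; the cause was not tested. Both settings were chosen after seeing the data. Not run, because the gene table gives neither strand, transcripts nor sequence, were the 5′ end of any transcript, matching on CpG ratio, gene bodies without the first 2 kb, distance from 5′ ends alone, and both settings of repeat content. Leaving out replicates and the settings for libraries, counts or normalised values per peak gave no value. No paired analysis was possible because the merged list names no library. Depth is unknown, so the absence of a peak cannot be told from too few reads.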

Other observations

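Other classes of genes differed widely in how often their ends were open. Transfer RNA genes had a peak at an end in 307 of 403 cases (76.2%, 71.8 to 80.1), which, at a median length of 72 bp, covers the whole gene. Long noncoding RNA genes had one in 45.3% of 12637 cases (44.5 to 46.2). Pseudogenes had one in 19.1% of 9853 cases (18.3 to 19.9), while those annotated as transcribed had one in 41.6% of 476 (37.3 to 46.1). The latter are longer, with a median of 3298 against 907 bp, so that their windows span more DNA, and single windows at the midpoints gave 20.0% against 13.4%. MicroRNA genes stood at 29.6% of 1228, small nucleolar RNA genes at 17.3% of 1330 and small nuclear RNA genes at 13.4% of 997. Lengths also differ between these classes, so their shares do not rest on equal spans of DNA. Long noncoding RNA genes had a median of 8459 bp and microRNA genes 80 bp, and single windows at midpoints gave 18.5% and 29.0%. In long genes, however, the midpoint lies far from the ends. Many small RNA genes lie inside other genes, whose peaks then count.

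The longest stretches without a peak lay on chromosome Y. It held 23 intervals of 1 Mb or more with no peak, with 144 protein-coding genes inside, Ssty2 among them, and the longest was 5.90 Mb (23530498 to 29429471). Of the 253 protein-coding genes on Y, 0.395% had a peak at an end, against 60.3% of the 956 on X outside the receptor and defensin families. Whether the cells carry Y, and whether reads can be placed in its sequence, cannot be told from this list. These absences on Y are therefore no evidence of closed chromatin. Outside Y no interval reached 1 Mb, and 98 reached 300 kb, with a longest of 0.759 Mb. Those 98 held 53 protein-coding genes, of which 0 were olfactory or vomeronasal receptors. Ssty2 was named after its position was seen.

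Of the tests that follow, the 1 on peaks within 10 kb of receptor genes was chosen only after the result was seen. No biological explanation was tested, since the groups of the study are times that the merged list does not carry.

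Few peaks lay at the ends of olfactory and vomeronasal receptor genes (4.87% of 1458). If annotated ends missed the promoters, peaks would lie nearby. Within 10 kb of an end, 44.5% of these genes had a peak against 93.5% of other genes. Receptor genes are short, with median lengths of 951 bp (olfactory) and 960 bp (vomeronasal) against 17219 bp over all protein-coding genes. Their windows overlap and span less DNA, so this comparison cannot decide. Loss of reads confined to the resembling gene copies would by itself spare the DNA 2 to 10 kb outside them. Peak density there was 0.308 times that beside other genes (bootstrap 95% interval 0.283 to 0.331). The bootstrap drew single genes, while receptor genes lie in clusters and can share flanks, so the interval may be too narrow. Such a loss would not account for the sparse flanks, but within them it could still act at the genes, so it stays open. Other genes matched on peaks 10 to 500 kb away had a peak at an end in 64.0% of cases. They were matched neither on gene length nor on nearer flanks. Random lists matched on gene length alone had 39.9% (olfactory) and 46.1% (vomeronasal), and could hold genes of the other receptor family. No comparison matched both, so sparse surroundings stay open too. A loss of reads that reaches the flanks, where clusters may also be duplicated, is open as well, as are promoters missed by the annotated ends. Closed chromatin at these genes is a hypothesis that this list cannot separate from any of these.

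Low peak density on chromosome X exceeded what its gene density would give. On a line of distal peak density against gene density over 19 autosomes, X lay at -20.3 peaks per Mb and the lowest autosome at -13.5, which argues against few genes as the whole cause. If the cells carry 1 copy of X, which the labels do not state, fewer reads could remove weak peaks. The share of X genes outside the receptor and defensin families with a peak at an end was 60.3%, below the lowest autosome at 70.1%, but the median width of gene-end peaks, 976.5 bp, lay within the autosomal range of 969.5 to 1109 bp. Copy number and lower accessibility of X cannot be told apart without read counts.

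Peaks wider than 4 kb lay near protein-coding ends less often than those somewhat narrower. The share was 15.4% (4 of 26 on assembled chromosomes) against 53.2% at 2 to 3 kb and 57.0% at 3 to 4 kb. It was not below the 2.82% of peaks up to 500 bp or the 6.73% of those of 500 to 1000 bp. Chaining of neighbouring calls by merging predicts crowded surroundings, but a median of 4 other peaks lay within 20 kb of the 30 peaks over 4 kb against 5 for 2953 peaks of 2 to 4 kb (permutation test, two-sided p = 0.457), so this explanation stays open. Multi-copy sequence that collects reads predicts clusters of wide peaks, and 23.3% (7 of 30) lay on contigs or within 20 kb of another such peak, against 0.880% (26 of 2953). Those 7 are not independent, as they come from 2 loci, 1 contig and a stretch near Gm21119 on chromosome 8. With so few loci no test was made, and this explanation stays open too.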
